A study of Micropterus salmoides with 16 samples.

How the data were processed

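Liver and testis RNA of adult male largemouth bass was hybridised to single-colour oligonucleotide arrays, 1 sample per array, giving 16 arrays in 4 groups of 4: liver saline, liver cadmium, testis saline and testis cadmium. Per the labels' protocols, total RNA was column-purified and DNase-treated, its quality was monitored on a Bioanalyzer, and it was amplified and labelled with a cyanine dye. Per the submitters' processing notes, the images were quantified with Agilent Feature Extraction 9.1; the file headers give software version 10.1.1.1 for all 16 arrays. Per the file headers, the processed intensity of a spot was background-corrected with spatial and multiplicative detrending and with surrogate values for spots near background, and an extended scanning range was used for the testis arrays and not for the liver arrays. The deposited intensity values are on a linear scale and were not scaled between arrays. A deposited table of log2 values for the series equalled log2 of the processed intensity minus 1 constant per array, with deviations of at most 5.085e-09; the constant lay near the array's median, the column medians lay between 0.045 and 0.073, and no rescaling or change of direction was found. The rule by which the authors chose that constant is not given in the sources used here.

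Each array held 15744 spots and 15208 probes of 60 bases, each present once. Control spots were left out. Spots marked as non-uniform or population outliers, 0 to 84 per array, were set to missing, and saturated spots were kept. The log2 processed intensity was scaled by subtracting each array's 75th percentile. For the cadmium comparisons, probes had to be well above background on at least 4 of the 8 arrays of the tissue; this held for 11714 probes in liver and 13788 in testis. The comparison of the tissues' responses needed this in both tissues, and the comparison of the tissues in saline in either. Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the probes tested, and a probe was called at an adjusted p below 0.05. Liver and testis were fitted apart for cadmium against saline. All 16 arrays, with 1 coefficient per group, served the difference between the tissues' responses and the tissue comparison. No covariate was used in these fits. These designs, the alternatives and the gene lists were fixed before the data were examined, except where said otherwise.

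All 15208 probes are described as unknown in the files and carry contig or sequence names. Only 58 probes were named by a sequence accession, 29 accessions in all, and 0 of these matched the 37622 genes of the reference table used here (assembly GCF_014851395.1). No probe was therefore given a gene name. The gene lists and cell type markers chosen beforehand, and the 3 list tests planned on them in liver, in testis and between the tissues, gave no value. The rule fixed beforehand chose genes by name and allowed, among probes with no name, at most 2 higher and 2 lower ones by identifier; only this last part could be applied, here to each comparison. How these were picked was set after the annotation was seen. For the cadmium comparisons and the difference between the tissues these are the probes with the smallest unadjusted p in each direction. For liver against testis they are those with the largest change among called probes whose 4 values of each group did not overlap. Where a probe was not well above background on any array of the dimmer group, the fold is a lower bound: the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal.

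In place of the gene lists, sets of probes at least 16-fold higher in liver or in testis and called (adjusted p below 0.05) were formed from the contrast of the tissues averaged over both treatments. These sets were added after the annotation was seen and were drawn from the same arrays. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusting over 4 tests.

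Slides and scan sessions were read from the headers. Each tissue lay on 2 slides of its own, each with 2 saline and 2 cadmium arrays, and liver and testis were scanned in separate sessions. Cadmium values were therefore also computed with slide as a block and within each slide. Tissue and slide, scan session and scanning range cannot be told apart.

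Alternatives were normexp background correction (offset 50), quantile normalization, median scaling, the deposited log2 values, no filter or a stricter filter on dim probes, an intensity trend, slide and replicate number as blocks, all 16 arrays in one fit, array weights, an unadjusted p below 0.05 with at least 1.5-fold change, and leaving out each array in turn. Added later were fits within each slide, array weights for the 2 comparisons across tissues, a fit of the 8 saline arrays alone, and removal of unequal signal over each array (each spot minus the median deviation of the spots around it in a window of 9 rows and 5 columns). The models were tested on simulated data: in 10 draws per comparison, 200 probes were given known changes on top of the real residuals with arrays reassigned, 50 probes each at 2-, 4-, 8- and 16-fold. Figures were drawn with matplotlib 3.10.9. The design text gives 4 fish per treatment, so the spread within a group was taken as the spread between fish, with array error included.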

Results

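Adult male largemouth bass (Micropterus salmoides), a freshwater sport fish, had been injected into the body cavity once with cadmium chloride at 20 µg/kg or with saline, and liver and testis were removed after 48 h. Transcript levels were measured on arrays of 15208 probes in 4 fish per treatment and tissue, to learn which transcripts a single low dose of this toxic metal alters. In liver, 67.2% to 80.3% of probes were well above background, and the 75th percentile of signal lay between 327 and 784 intensity units. In testis the range was 65.2% to 94.1%, and the 75th percentile lay between 1205 and 3053 units. The 4 testis arrays of slide 1 had 65.2% to 80.6% of probes well above background and those of slide 4 had 90.6% to 94.1%. The number of arrays limits the precision of every value below. The files pair none of the probes with a gene name, so transcripts are given by probe identifier and by the probe's sequence, without a function. Levels are log2 signal relative to the array's 75th percentile.

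The first comparison asked which liver transcripts differed 48 h after cadmium. The probes with the smallest p on the higher side were UF_Msa_AF_108386 and UF_Msa_AF_104244. UF_Msa_AF_108386 (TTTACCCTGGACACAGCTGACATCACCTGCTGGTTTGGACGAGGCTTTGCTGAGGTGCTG) had a level of -0.25 ± 0.645 (SD, n = 4) with cadmium and -3.01 ± 0.694 (SD, n = 4) with saline, a difference of 6.8-fold, and all 4 cadmium values lay above all 4 saline values. UF_Msa_AF_104244 (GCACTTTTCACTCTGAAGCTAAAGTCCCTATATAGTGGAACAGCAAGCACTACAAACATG) had 7.18 ± 0.031 (SD, n = 3) with cadmium and 3.66 ± 0.985 (SD, n = 3) with saline, an 11.5-fold difference over the 3 fish of each treatment whose spots were not excluded as outliers. On the lower side, UF_Msa_AF_105798 (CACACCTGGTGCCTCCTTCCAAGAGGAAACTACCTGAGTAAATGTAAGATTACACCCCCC) had -0.94 ± 0.171 with cadmium and 0.24 ± 0.293 with saline (SD, n = 4 each), and UF_Msa_AF_106761 (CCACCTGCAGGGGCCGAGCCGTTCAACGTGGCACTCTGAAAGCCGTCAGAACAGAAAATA) had -3.27 ± 0.296 and -1.99 ± 0.316 (SD, n = 4 each). None of these differences passed the adjustment for the 11712 probes tested: the adjusted p of each was 0.949 in limma. The log2 changes within slides 2 and 3 were 2.12 and 3.41 for UF_Msa_AF_108386, 4.54 and 2.99 for UF_Msa_AF_104244, -1.07 and -1.29 for UF_Msa_AF_105798, and -1.37 and -1.19 for UF_Msa_AF_106761. Here and in the cadmium comparisons below, the named probes were picked for a small p on these same arrays. Values that do not overlap and equal signs on both slides follow largely from that choice and are no independent support. Processing also moved the sizes: the smallest log2 changes over the alternatives were 1.94 for UF_Msa_AF_108386, -0.95 for UF_Msa_AF_105798 and -0.72 for UF_Msa_AF_106761, all with normexp, and 2.38 for UF_Msa_AF_104244 with unequal signal over each array removed.

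Across all liver probes, limma called 0 at an adjusted p below 0.05. At an unadjusted p below 0.05, 5% of probes would be expected if no transcript changed and the model's assumptions held. On these arrays a lower share was usual. Over the 35 splits of the liver arrays into groups of 4, the real one included, the median count was 357, also below 5%. The real count was 335 probes, 2.86% of those tested, of which 160 were higher and 175 lower with cadmium. This balance went either way with the processing and with single arrays. It was 132 higher and 239 lower with quantile normalization, 104 and 247 with median scaling, 102 and 258 with the deposited log2 values, 172 and 153 with normexp, and 357 and 286 with all 16 arrays in one fit. With 1 array left out, 85 to 331 were higher and 113 to 340 lower, with 331 and 288 without saline replicate 2, 270 and 340 without saline replicate 4, 119 and 113 without cadmium replicate 1, and 85 and 116 without cadmium replicate 3. With slide as a block the counts were 0 called and 328 at the unadjusted threshold. The unadjusted count was 619 without saline replicate 2, 610 without saline replicate 4 and 201 without cadmium replicate 3, with 0 called in each case. The median half-width of the 95% interval of a change was 0.996 on the log2 scale, or 1.99-fold. When known changes were added to the liver residuals, 0.8% of 2-fold, 29.2% of 4-fold, 62.6% of 8-fold and 74.8% of 16-fold changes were recovered. A 2-fold response of single transcripts would thus mostly be missed with these arrays. Here and below, changes of all sizes were added at once, which eases the adjusted threshold. The shares may therefore be too high for a response of few transcripts, which was not simulated. The median number of false calls per draw was 1.5 in liver and 1.5 in testis.

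**Figure D1:**
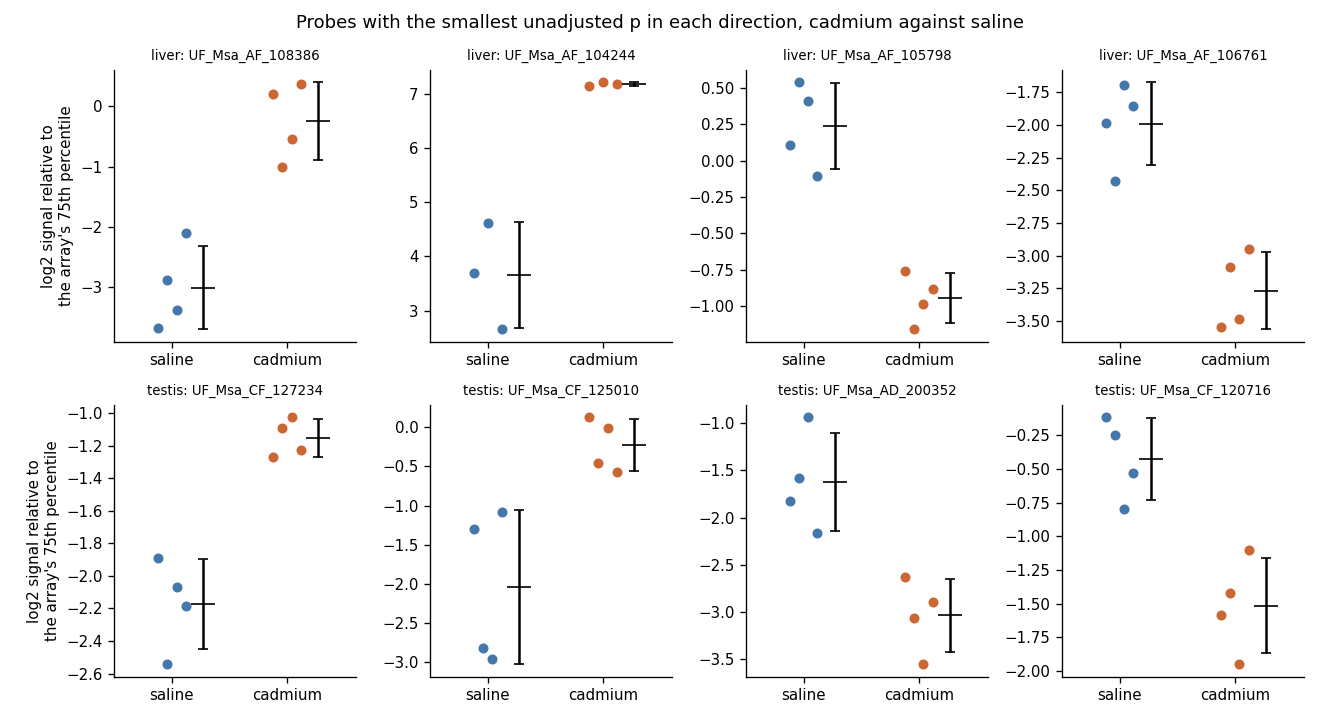
Log2 signal relative to the array's 75th percentile (vertical axis, a separate range in each panel) for liver (top) and testis (bottom), in each the 2 higher and the 2 lower probes with the smallest unadjusted p of their direction for cadmium against saline; points are fish, and horizontal bars with whiskers are means ± SD. The cadmium and saline points of each panel do not overlap, and none of the 8 probes passed the adjusted threshold (adjusted p of 0.949 in liver and 1 in testis). The probes were picked by p on these same arrays, so the separation of the points is no independent evidence.

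The same comparison was made in testis. UF_Msa_CF_127234 (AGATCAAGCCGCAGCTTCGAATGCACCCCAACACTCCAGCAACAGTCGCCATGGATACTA) had a level of -1.15 ± 0.115 with cadmium and -2.17 ± 0.275 with saline (SD, n = 4 each), a 2.03-fold difference. UF_Msa_CF_125010 (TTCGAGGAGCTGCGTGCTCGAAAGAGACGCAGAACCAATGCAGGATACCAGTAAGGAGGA) had -0.22 ± 0.336 and -2.04 ± 0.988, a 3.52-fold difference, with 3 of the 4 saline values well above background. On the lower side, UF_Msa_AD_200352 (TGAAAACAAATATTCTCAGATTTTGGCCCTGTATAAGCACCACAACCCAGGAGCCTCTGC) had -3.04 ± 0.389 with cadmium and -1.63 ± 0.521 with saline, and UF_Msa_CF_120716 (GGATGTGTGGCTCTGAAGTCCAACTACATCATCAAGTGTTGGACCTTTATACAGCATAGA) had -1.52 ± 0.353 and -0.42 ± 0.304. The limma adjusted p of each of the 4 probes was 1. Within slides 1 and 4 the log2 changes were 1.12 and 0.91 for UF_Msa_CF_127234, 2.73 and 0.90 for UF_Msa_CF_125010, -1.6 and -1.23 for UF_Msa_AD_200352, and -0.98 and -1.2 for UF_Msa_CF_120716. With normexp the log2 change was 0.33 for UF_Msa_CF_127234 and 0.82 for UF_Msa_CF_125010, against 1.02 and 1.82, and the change of UF_Msa_AD_200352 was -0.99 with unequal signal removed, against -1.41.

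Of 13788 testis probes tested, limma called 0, and 177 (1.28%) had an unadjusted p below 0.05, of which 64 were higher and 113 lower with cadmium. This share, too, was below 5%, but so was the median count of 435 over the 35 splits of the testis arrays. With normexp, which moved the median of all changes to -0.29, 8 were higher and 80 lower. With 1 array left out, 37 to 125 were higher and 79 to 176 lower. The counts were 106 and 120 without saline replicate 1, 109 and 95 without saline replicate 2, 125 and 118 without saline replicate 4, 37 and 100 without cadmium replicate 1, 99 and 102 without cadmium replicate 3, and 67 and 176 without cadmium replicate 4. With slide as a block, 0 were called and 262 passed the unadjusted threshold. The median half-width of the 95% interval was 0.85, or 1.8-fold. Of changes added to the testis residuals, 1.8% of 2-fold, 43.4% of 4-fold, 65.2% of 8-fold and 85.6% of 16-fold changes were recovered.

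**Figure D2:**
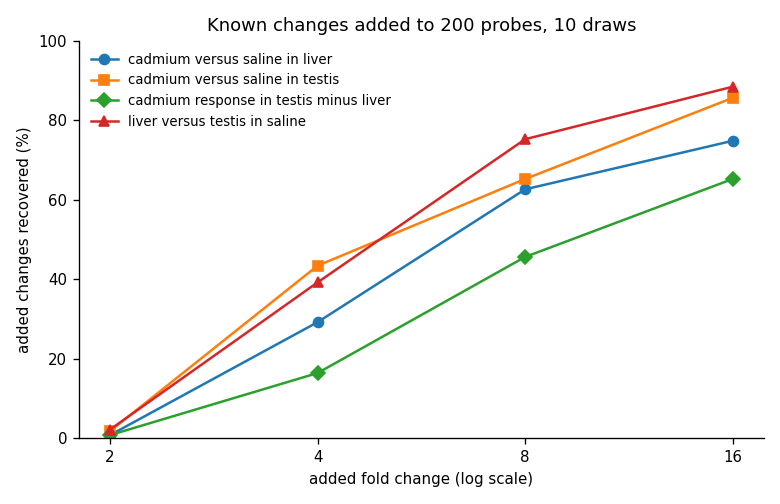
Percentage of known changes recovered at an adjusted p below 0.05 (vertical axis) against the size of the added fold change (horizontal axis, log scale) for the 4 comparisons, each from 10 draws of 200 changed probes. At 2-fold the recovered share was at most 2.2%. At 16-fold it was 65.2% for the difference between tissues and 74.8% to 88.4% for the other comparisons. Changes of all sizes were added in the same draw, so the shares may be too high for a response of few transcripts.

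The slides gave a check of the cadmium change on separate fish. Across 11598 liver probes, the log2 changes of slides 2 and 3 correlated with r = 0.0334, and 51.5% of probes had the same sign on both. Across 13617 testis probes, the changes of slides 1 and 4 correlated with r = 0.0385, and 50.7% had the same sign. Probes are not independent replicates, so the treatments were relabelled within the slides: 7 of 18 relabellings in liver (exact permutation p = 0.389, one-sided) and 5 of 18 in testis (exact permutation p = 0.278, one-sided) gave a correlation as high, where the smallest p possible is 0.0556. The design could not reach 0.05 in this test.

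**Figure D3:**
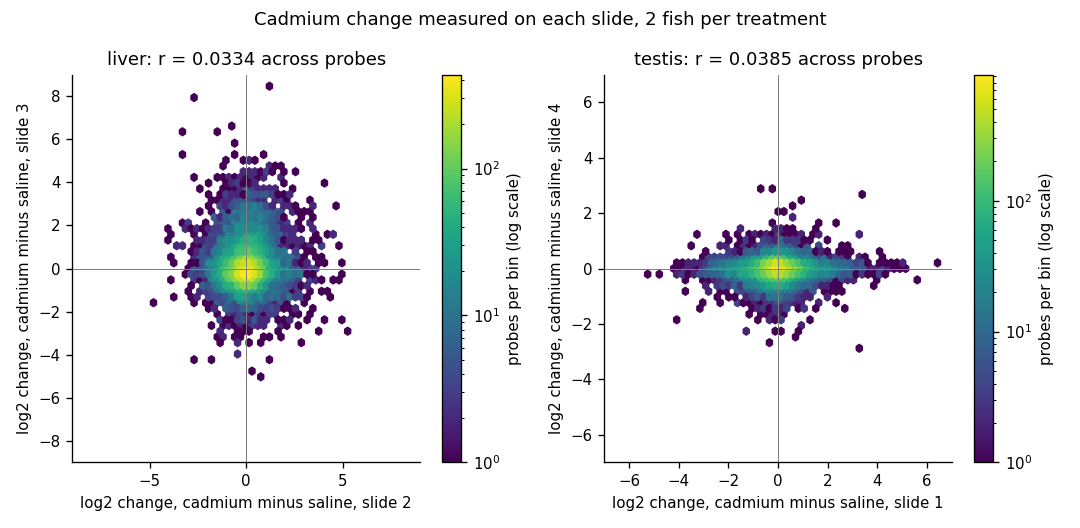
Log2 change with cadmium on one slide against that on the other for each liver probe (left, slides 2 and 3) and testis probe (right, slides 1 and 4); each bin is coloured by its number of probes on a log scale, and each change is the mean of 2 cadmium fish minus the mean of 2 saline fish. The correlations across probes are 0.0334 in liver and 0.0385 in testis, and the testis changes spread more widely on slide 1 than on slide 4.

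The difference between the tissues in the response to cadmium was tested in one model over all 16 arrays. UF_Msa_AF_107649 (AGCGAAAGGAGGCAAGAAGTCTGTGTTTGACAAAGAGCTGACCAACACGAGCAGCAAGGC) had a log2 change of 0.60 in testis and -0.79 in liver, and UF_Msa_AF_100897 (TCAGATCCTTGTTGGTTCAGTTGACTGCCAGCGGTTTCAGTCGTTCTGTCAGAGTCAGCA) had 0.76 and -1.04. Within testis slides 1 and 4 the changes were 0.90 and 0.30 for UF_Msa_AF_107649 and 1.44 and 0.07 for UF_Msa_AF_100897, and within liver slides 2 and 3 they were -0.75 and -0.84, and -1.02 and -1.07. In the other direction, UF_Msa_AF_108386, the probe that led the higher side in liver, changed by 0.41 in testis and 2.76 in liver, a difference of -2.36 ± 0.607 (SE), with testis changes of 0.74 within slide 1 and 0.08 within slide 4. UF_Msa_AF_108719 (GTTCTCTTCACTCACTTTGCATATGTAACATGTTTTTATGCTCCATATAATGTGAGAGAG) had a fitted log2 difference of -8.29 ± 1.88 (SE). Its testis level was 3.58 ± 3.58 (SD, n = 4) with saline and -2.72 ± 1.46 (SD, n = 3) with cadmium, and in liver it was well above background on 3 of 4 cadmium arrays and 1 of 4 saline arrays, so the liver part of the difference was measured from background. Its log2 change was -4.31 within slide 1 and -8.17 within slide 4 in testis, and 1.21 within slide 2 and 2.79 within slide 3 in liver. With normexp the difference was 0.71 for UF_Msa_AF_100897, against 1.80, and -6.39 for UF_Msa_AF_108719. The limma adjusted p of each of these 4 probes was 0.995. Without testis saline replicate 3, UF_Msa_AF_108719 alone passed, with a log2 difference of -10.1 and an adjusted p of 0.00019. Over all alternatives for this probe the adjusted p lay between 0.00019 and 1. In the fit of testis alone without that array, limma called 0 probes, with a smallest adjusted p of 0.169. Of 11493 probes, limma called 0, and 257 (2.24%) had an unadjusted p below 0.05, against 5% expected if no response differed. The median count over 100 drawn relabellings was 436, also below 5%. With slide as a block the counts were 0 and 286. The unadjusted count was 506 without liver saline replicate 2 and 490 without liver saline replicate 4. Of changes added to one tissue's response, 16.4% of 4-fold, 45.6% of 8-fold and 65.2% of 16-fold changes were recovered.

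Liver and testis of the saline fish differed in a large part of the transcripts measured. The probes with the largest fitted changes in each direction are given with lower bounds, which do not rank them and hold for the 75th-percentile scaling of the processed intensity only. On the liver side these were UF_Msa_AF_106430 (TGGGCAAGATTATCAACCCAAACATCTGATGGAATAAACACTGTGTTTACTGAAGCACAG), at least 4530-fold higher in liver, and UF_Msa_AD_200128 (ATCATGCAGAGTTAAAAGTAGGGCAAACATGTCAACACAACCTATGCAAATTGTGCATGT), at least 6000-fold higher in liver. Both were not well above background on any saline testis array and were saturated on 3 and 4 saline arrays of liver. In testis, UF_Msa_CF_120783 (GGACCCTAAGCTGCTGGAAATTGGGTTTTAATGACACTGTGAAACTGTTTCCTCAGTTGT) was at least 651-fold higher and UF_Msa_AF_103155 (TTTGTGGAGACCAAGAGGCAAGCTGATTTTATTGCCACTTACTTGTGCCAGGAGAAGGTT) at least 697-fold higher, and both were not well above background on any saline liver array. The limma adjusted p was 1.34e-07 for UF_Msa_AF_106430, 3e-12 for UF_Msa_AD_200128, 2.15e-10 for UF_Msa_CF_120783 and 8.31e-10 for UF_Msa_AF_103155. With normexp the fitted log2 changes of these 4 probes were nearer 0 than the bounds: at most 10.3 for the 2 liver probes, against 14.21 and 13.87, and -6.32 and -6.58 for the testis probes, against -10.77 and -10.62. Of 14005 probes, 7264 were called, 2263 higher in liver and 5001 higher in testis, a liver share of 31.2%. This split moved with the scaling and the filter, and the median of all changes was -0.62 on the log2 scale. The liver share was 41.6% of 4228 calls with normexp, 47.4% of 5571 with quantile normalization, 58.7% of 6925 with median scaling, where the median change was 0.17, and 59.0% of 6918 with the deposited log2 values. With the scaling kept and only probes well above background on all arrays, it was 47.4% of 3800, with a median change of -0.02. Under all 5 scalings alike, 1211 probes were called higher in liver and 1635 higher in testis, and 79 were called in opposite directions by different scalings. Tissue and slide, scan session and scanning range cannot be told apart in these arrays.

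Probes characteristic of each tissue were then followed under cadmium. The 424 liver-enriched probes measured in liver had a median log2 change of 1.13 with cadmium, 386 of them higher, and 0 were called, also when adjusted over the set alone. The set differed from the other probes in camera at a preset correlation (adjusted p = 2.67e-22) and did not at an estimated correlation (adjusted p = 0.39), with a correlation of 0.462 between its probes. Relative to the mean of the 8 liver arrays, the set's median was -3.25 in liver saline replicate 3 and 0.01 to 0.91 in the other 7. Without that array the median change was 0.24, so much of the value came from it, but not all. With slide as a block the median change was 1.13. It was 0.58 within slide 2, which did not hold liver saline replicate 3, and 1.79 within slide 3, which did. In testis, the 630 testis-enriched probes had a median change of 0.24, with 495 higher and 0 called (camera adjusted p = 1.82e-09 at the preset and 0.39 at the estimated correlation). Here the set's median was -1.07 in testis saline replicate 2 against 0.07 to 0.36 in the other 7 arrays, and without that array the median change was -0.08. It was 0.24 with slide as a block, 0.49 within slide 1 and -0.0014 within slide 4. Testis-enriched probes in liver had a median change of 0.03 (295 probes, camera adjusted p = 0.823 at the preset correlation) and liver-enriched probes in testis one of -0.10 (363 probes, camera adjusted p = 0.153). With slide as a block these medians were 0.03 and -0.10. They were -0.16 and 0.17 within liver slides 2 and 3, and -0.08 and -0.07 within testis slides 1 and 4. The sets were drawn from these same arrays and are no independent evidence of a direction. Saturated spots were kept and cannot show a full change. Of 442 liver-enriched probes defined without liver saline replicate 3, 262 were saturated on no liver array. How saturation moved the values of the liver-enriched set in liver was not tested.

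**Figure D4:**
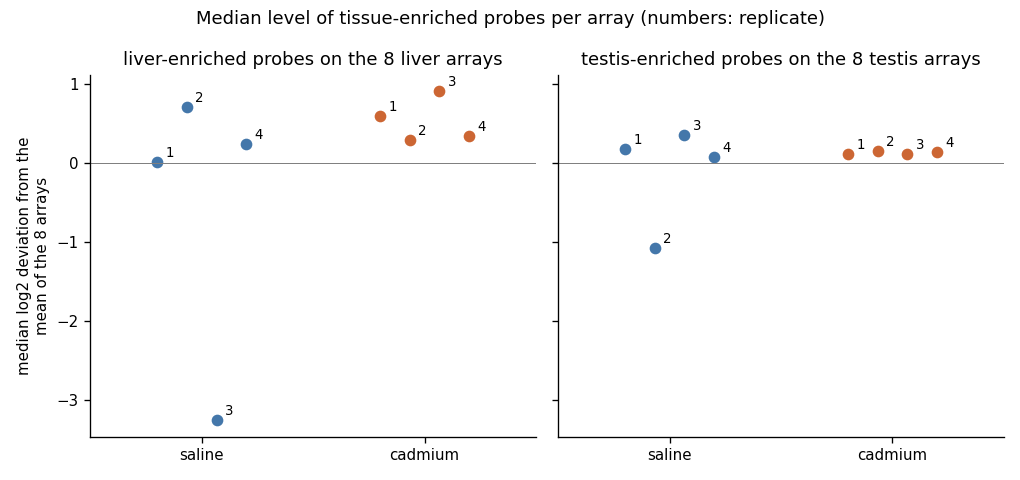
Median log2 deviation from the mean of the 8 arrays of the tissue (vertical axis) of liver-enriched probes on the liver arrays (left) and testis-enriched probes on the testis arrays (right); each point is 1 fish, labelled with its replicate number. Liver saline replicate 3 lies at -3.25 and testis saline replicate 2 at -1.07, below the other 7 arrays of their tissue.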

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

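In 65 groups of 4 arrays (quality measures, set medians and levels of the named probes), 1 sample lay farther from the others of its group than chance places it in about 1 of 20 groups; chance alone would give about 3.2 such groups. It was UF_Msa_AF_108719 in testis saline replicate 3, whose log2 level was -1.78, while the other 3 saline testes lay between 5.2 and 5.5. The 3 measured cadmium testes lay at -2.51, -1.37 and -4.27, and the spot of cadmium replicate 2 was an outlier spot and not used. The probe's log2 change in testis was -6.29 ± 1.82 (SE), with a limma adjusted p of 1. No test separated a technical from a biological source of the low saline value. No probe's response to cadmium differed between liver and testis at an adjusted p below 0.05 in limma, with 257 probes at an unadjusted p below 0.05.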

How the results depend on the processing

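The alternatives limited to one slide, to the saline arrays, with array weights across tissues or with unequal signal removed, and all those for the tissue-enriched sets, were chosen after seeing the data. The count of calls for cadmium was 0 in liver and in testis under every alternative at the adjusted threshold and without each of the 8 arrays in turn, and at an unadjusted p below 0.05 with at least 1.5-fold change it was 333 in liver, 173 in testis and 257 for the difference between the tissues. Without the fold requirement the counts were 335, 177 and 257, each below 5% of the tested probes. The median counts over splits or relabellings of the arrays, 357, 435 and 436, were below 5% as well. The difference between the tissues kept 0 calls under its other alternatives, and leaving out each array gave 0 to 1 calls, the 1 being UF_Msa_AF_108719 without testis saline replicate 3 (log2 difference -10.1, adjusted p 0.00019); the change follows from leaving out the one low saline value. The liver against testis count of 7264 fell to 4228 with normexp and to 3800 with probes well above background on all arrays, where 7487 probes were tested; the cause of the former was not tested. Of the normexp calls, 4106 were also called in the main setting, all in the same direction, and of the 5571 quantile calls, 4310 were, 4292 of them in the same direction. The named probes kept their direction wherever they were tested, while their sizes moved. They were picked on these same arrays, so a kept direction is largely a result of the choice and no independent support.

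Unadjusted counts moved more. In liver they were 222 with the replicate block, 643 with all 16 arrays, 836 with array weights and 201 to 619 with 1 array left out. In testis they were 88 with normexp, 379 with array weights, 307 on slide 1 alone and 408 on slide 4 alone. Between the tissues they were 694 with array weights and 196 to 506 with 1 array left out. Normexp also moved the median of all testis changes to -0.29, that of the difference between the tissues to -0.29 and that of liver-enriched probes in testis to -0.55.

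With the replicate block, 0 probes were called in liver, testis and between the tissues and 7331 between liver and testis in saline. Saline and cadmium fish of one number are different fish. Liver and testis of one number correlated in their deviations by -0.055 to 0.078, not above 0.1 in any pair, with a consensus correlation of 0.033 and 0.023 in the blocked fits. In the 4 saline pairs the correlations were 0.032 to 0.078 and the testis array of the same number was the closest match, which held in 0 of the 4 cadmium pairs, so whether the numbers pair tissues of 1 fish stays open. The planned tests of gene lists and their alternatives were not run, since no probe has a gene name. The SD of negative controls was 9.77 to 16.9 intensity units on testis slide 1 and 4.45 to 6.95 on slide 4, and 65.2% to 80.6% of probes on slide 1 and 90.6% to 94.1% on slide 4 were well above background.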

Other observations

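The tests with array weights and the splits of the called counts for cadmium were chosen after the results they measure were seen. Also added after a first value had been seen were the level of testis-enriched probes that the needed share of testis RNA predicts, the bootstrap interval for poly(A) signals, the splits of the weighted fits and the reading of set medians by their quartiles. Dilution was proposed after the fall of liver-enriched probes had been seen, before their spread was measured. The share of each testis array's signal held by its 100 brightest probes was 26.1% ± 1.39 with saline and 26.1% ± 1.3 with cadmium (SD, n = 4 each; exact permutation p = 1, two-sided). No such share is given for liver, where 146 to 303 spots were saturated on each array. Across the 16 arrays, 27 probes were well above background on all 8 liver arrays and no testis array, 161 on all 8 testis arrays and no liver array, and 7489 on all 16. No liver probe was well above background in all 4 fish of one treatment and in none of the other, and 1 testis probe was, in the cadmium fish. Other splits of the testis arrays reached 803 such probes, and of the liver arrays 64.

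Liver saline replicate 3 stood apart from the other liver arrays, with a median correlation of 0.846 against 0.906 to 0.937 for the others and a median fall of 12.7-fold over 442 liver-enriched probes defined without it. On the log2 scale this median was -3.66, and it was -3.64 over the 262 of these probes that were saturated on no liver array. RNA from testis large enough for that fall, a share of 92.1%, would raise 539 testis-enriched probes by a median of 5.1, while their median deviation was 0.323 with an upper quartile of 1.02. Even dilution by RNA lacking these transcripts would lower all unsaturated liver-enriched probes alike. The interquartile range of their deviations was 2.64 times that of the other liver arrays, which goes against it. Probes that reach background stop falling, however, which also widens the range, and this was not checked. Even dilution is therefore not excluded. A dim array was argued against by the SD of 2.16 times the others over the 3866 brightest probes. Loss of the RNA's 5' parts would leave probes with a poly(A) signal higher, and their median deviation minus that of the other probes was -0.127 (95% bootstrap interval -0.216 to 0.0078). This interval resamples the probes of 1 array and does not measure the spread between arrays. That these probes lie near the 3' end was assumed and not checked. The value gave no sign of such loss but cannot exclude it. A difference of this fish's liver in state may remain as an explanation and was not tested. A tissue other than testis in the piece was tested only as even dilution, which was not excluded, and a tissue that holds some of these transcripts may also remain.

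Testis arrays of slide 1 differed more from each other (pairwise r of 0.853 to 0.894 across probes) than those of slide 4 (0.972 to 0.981). Signal close to background was argued against as the cause, since the SD of differences between fish of one treatment was 3.12 times higher on slide 1 over the 4539 brightest probes and 1.86 times over the 4539 dimmest. The deviations of neighbouring spots correlated with a median r of 0.401 on the slide 1 arrays (0.242 to 0.499), consistent with patches of unequal signal that the deposited detrending left. The 4 arrays of slide 4 had 0.2 to 0.229 and the liver arrays 0.147 to 0.471, so such correlations were not limited to slide 1. Each deviation was taken from the mean of the other arrays of the tissue, so patches on slide 1 also enter the slide 4 values. Those values therefore do not show patches on slide 4 itself. Subtracting the median deviation of the spots around each spot left 0 calls in testis and 161 probes at an unadjusted p below 0.05. Whether this took the patches away was not measured, and a difference between the fish of the slides stays open.

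The cadmium comparisons had 0 calls in limma, which leaves nothing for chance to explain: any split gives at least 0, as did all 35 in liver (highest other 1), all 35 in testis (highest other 1018) and all 100 drawn relabellings for the difference between the tissues (highest other 69). Chance could not be excluded for the counts at an unadjusted threshold. For probes at an unadjusted p below 0.05, 22 of 35 splits in liver gave at least the real 335 (highest other 1058), 28 of 35 in testis at least 177 (highest other 2727), and 85 of 100 between the tissues at least 257 (highest other 1115). The median count over the splits was 357 in liver, 435 in testis and 436 between the tissues, each above the real count. Among the 18 splits with 2 arrays of each group on each slide, 10 in liver (highest other 1058) and 11 in testis (highest other 840) gave at least the real count. The testis split with 1018 and 2727 probes was that by slide. Each slide held its own fish, so a difference of arrays and one of fish cannot be told apart here. With slide as a block 0 probes were called for cadmium. For liver against testis in saline, 1 of 35 splits, the real one, reached 7264 calls, and the highest other gave 151. A share of 1 in 35 is the smallest this test can give, so chance is unlikely but not excluded. Every other split mixed liver and testis arrays within a group, which widens the spread and leaves few calls. Slide, scan session and scanning range divide the arrays in the same way as tissue.

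A wide spread of a few arrays may hide liver differences: with array weights 7.14% of liver probes had an unadjusted p below 0.05, but 9 of 35 splits gave a share as high under the same weights (highest other 10.7%, median 5.35%), which leaves this open. In testis the share with weights was 2.75%, which 34 of 35 splits reached under the same weights (median 7.34%), so the weights brought out no excess of small p-values there. The hypothesis of a cadmium response shared by the fish of both slides was left open by correlations of 0.0334 in liver and 0.0385 in testis. Both were above the median of 0 over the 18 relabellings and neither was the highest. The relabellings include every mirror image, so their median of 0 is fixed in advance and lying above it shows only a positive sign. A response shared by liver and testis was left open by a correlation of 0.0213 across 11259 probes, which 33 of 100 relabellings reached. Median changes of the tissue-enriched sets (1.13 and 0.0258 in liver for liver- and testis-enriched probes, -0.0989 and 0.244 in testis) did not settle whether such transcripts move together, since the estimated-correlation adjusted p was 0.39 for 3 of the sets and 0.938 for testis-enriched probes in liver, and the 2 medians nearest 0 came from members that went both ways, with quartiles of -0.367 and 0.341 in liver and -0.504 and 0.286 in testis. The SD between fish of liver probes with an identical copy was 2.75 times the SD between the copies on one array (45 pairs), and the ratio in testis was 1.47 (44 pairs). These liver probes had a median SD between fish of 1.1, against 0.633 over all liver probes. Copies share the labelling and hybridisation of their array, so this does not separate fish from arrays.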
